A study of Homo sapiens with 8 samples.

How the data were processed

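RNA abundance was measured in 8 libraries from TAMR, a tamoxifen-resistant derivative of the MCF7 breast cancer line that is kept in 4-hydroxytamoxifen. Tamoxifen blocks the estrogen receptor, and decitabine is a deoxycytidine analogue that is built into DNA and traps DNA methyltransferases, so that methylation is lost as cells divide. The labels define 4 groups of 2 libraries each. Decitabine Day 7 cells received 100 nM decitabine on each of 7 days and were harvested on day 7. Decitabine Recovery cells received the same course and were then grown without drug until day 35. Untreated cells were harvested on day 11 as Control Early and on day 35 as Control Late. The treatment protocol gives the drug-free period as 28 days and the series' design text gives 21 days. The sample descriptions and the deposited columns name both late groups by day 28, which goes with the design text. Day 35 is used here as the protocol gives it, and the conflict is unresolved. The deposited columns also call the drug Aza, where the labels and the protocol name decitabine, and columns were matched to samples through the sample descriptions. The early control and the treated cells of day 7 were thus harvested on different days of culture. Per the labels' protocols, RNA was extracted with a phenol-based reagent, poly(A) RNA was converted to stranded libraries with the TruSeq kit, and libraries were sequenced on a NovaSeq in paired-end mode. The labels do not say whether the replicates of a group were separate cultures, so p-values measure only the spread between these samples, which may be technical.

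The authors deposited TPM, a transcript abundance corrected for length and scaled to a fixed total, for 229580 transcripts in each library, rounded to 2 decimals, and each library summed to 1000000 TPM with mitochondrial transcripts included. The submitters' processing notes name Trim Galore 0.11.2, STAR 2.7.7a, DESeq2 without a version, and the genome build hg38 (GRCh38). The tool that estimated transcript abundance, its annotation release and whether it used the strand of the reads are not given in the sources used here. Promoter capture Hi-C and methylation arrays of the same series were not analysed here. TPM keeps no record of read depth, so the depth is unknown, no counting interval is given, and a value of 0 sets no upper limit.

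Transcripts were assigned to genes with GENCODE release 44 on GRCh38 by their Ensembl identifiers without the version. Of the transcripts, 226459 (98.6%) matched, 215561 of them with the same version. The 3121 unmatched transcripts held 0.390% ± 0.00902 (SD, n = 2) of the TPM in Decitabine Day 7 and 0.571% ± 0.00336 (SD, n = 2) in Control Early, and were left out of gene sums. TPM was summed over the transcripts of each of 61264 genes, and the 160 transcripts of the pseudoautosomal Y copies were added to their X counterparts. Sums for genes with a near-identical copy (PAGE2, PAGE2B, SSX1 and others of the cancer-testis list, TUBA3D, and KRT17 with its pseudogenes) and for overlapping or antisense genes (TRG-AS1 and the TRGV genes) are uncertain, because reads could be split between them.

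The main test was limma-trend (limma 3.58.1 in R 4.3.3 with data.table, version 1.17.8) on log2(TPM + 1), two-sided, fitted to all 8 libraries with a mean per group and 4 residual degrees of freedom. Genes with at least 1 TPM in at least 2 libraries were kept, which left 14570. Where results are given without this filter, genes with any TPM in at least 1 library were tested. Values were not rescaled between libraries. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. All log2 fold changes are on the log2(TPM + 1) scale, which understates the change of genes with low values. The contrasts were Decitabine Day 7 minus Control Early, Decitabine Recovery minus Control Late, the difference between these effects, and Control Late minus Control Early. The same fit was made on 46360 single transcripts.

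Gene lists numbering 24 and holding 1065 names were fixed before the data were examined, as were the design, most alternative settings and the rule for named genes. Of the names, 30 matched no gene. Primary lists were cancer-testis antigens, interferon-stimulated genes, MHC class I presentation, estrogen response, proliferation and p53 targets. Secondary lists were germline genes controlled by methylation, genes silenced in breast tumours, imprinted genes, the DNA methylation machinery, chromatin looping factors, silencing complexes, luminal identity, basal and mesenchymal genes, fibroblast and endothelial markers, leukocyte markers, cholesterol synthesis, hypoxia and glycolysis, stress response, immediate early genes, growth factor receptors, ribosomal proteins, mitochondrially encoded genes and replication-dependent histones. Lists were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the 24 lists of a comparison, and again with the correlation estimated from the data. Members were also counted with p-values adjusted over the list alone.

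Named genes were taken by rule. In each of the day 7 and recovery comparisons these were the 10 genes with the largest rise and the 8 with the largest fall among called genes whose treated values both lay beyond both control values and whose higher group reached a mean of 5 TPM. Culture time and the difference of effects gave 5 each way. Each list gave up to 4 measured members with the largest change, and DNMT1, DNMT3A, DNMT3B, UHRF1, TET1, ESR1, FOXA1, GATA3, GREB1, PGR, TFF1, CDKN1A and MKI67 were always eligible. The text leaves out some genes that the rule took.

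Alternative settings fixed at that time were pseudocounts of 0.1 and 5, no filter or a mean of at least 5 TPM, median-of-ratios scaling, quantile normalization, limma without the trend or with robust estimation, a fit to only the 4 libraries of a comparison, a replicate block, a test against a 2-fold change, fry, and leaving out each library in turn. Alternatives chosen after seeing the data were rescaling to nuclear genes only, the control of the other time with and without median-of-ratios scaling, and removal of each library's trend with transcript length. Tests were first tried on simulated data for the day 7 comparison over 14570 genes. Of 100 genes changed 2-fold 99% were recovered, and of 100 genes changed 4-fold 100% were recovered, with 11 false calls. When all genes of the simulated treated libraries were lowered together, the unscaled fit made 11364 false calls and median-of-ratios scaling made 10. All genes were lowered by the same factor, which this scaling removes by design. In the data the median change at day 7 ran from -0.25 in the shortest sixth of protein-coding genes to -0.95 in the longest. The simulation therefore cannot show that scaled values of the data are sound. In a separate simulation without that lowering, a list shifted by -0.5 was called and 0 of 23 others were. Genes varied independently of each other there, so it cannot show how the list test behaves with correlated genes. Tables were handled with pandas 2.3.3 in Python 3.11.15 and figures drawn with matplotlib 3.10.9.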

Results

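Expression was measured in TAMR cells, a tamoxifen-resistant derivative of MCF7, in 4 groups of 2 libraries: Control Early, Decitabine Day 7, Control Late and Decitabine Recovery. The series asks how loss of DNA methylation under decitabine relates to gene regulation, and the 2 main comparisons set each treated group against the untreated group that the treatment protocol pairs with it. TPM values keep no depth, so the depth of each library is unknown. Between 100103 and 106357 transcripts lay above 0 in a library, and 13050 to 13660 genes reached 1 TPM. Replicates correlated across genes at 0.994 in Control Early, 0.992 in Decitabine Day 7, 0.986 in Control Late and 0.989 in Decitabine Recovery. The SD over genes of the log2 difference between replicates was 0.227 in Control Early and 0.355 in Control Late, the widest of the groups.

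Transcripts of the mitochondrial genome made up a larger part of the RNA after 7 days of decitabine. Their share was 26.9% ± 1.22 (SD, n = 2) of TPM in Control Early and 45.3% ± 1.37 (SD, n = 2) in Decitabine Day 7. At day 35 it was 25.1% ± 6.31 (SD, n = 2) in Control Late, whose libraries stood at 20.7% and 29.6%, and 33.4% ± 0.797 (SD, n = 2) in Decitabine Recovery. Histone genes expressed during DNA replication held 0.0689% ± 0.00336 (SD, n = 2) of TPM in Control Early and 0.154% ± 0.00567 (SD, n = 2) in Decitabine Day 7. The day 35 values were 0.0694% ± 0.00666 (SD, n = 2) in Control Late and 0.0665% ± 0.00512 (SD, n = 2) in Decitabine Recovery. Libraries were made from poly(A) RNA, so these values count only the histone transcripts that this selection captured. Ribosomal protein genes held 14.6% ± 0.324 (SD, n = 2) in Control Early, 13.1% ± 0.209 (SD, n = 2) in Decitabine Day 7, 16.5% ± 2.34 (SD, n = 2) in Control Late and 13.7% ± 0.0870 (SD, n = 2) in Decitabine Recovery. Because TPM has a fixed total, a larger mitochondrial share lowers the values of nuclear genes. The median gene lay at -0.54 on the log2 scale in the day 7 comparison and at -0.10 in the recovery comparison. Median-of-ratios scaling moved these medians to about 0, and changes at day 7 are therefore also given relative to that shift, as scaled values.

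**Figure D1:**
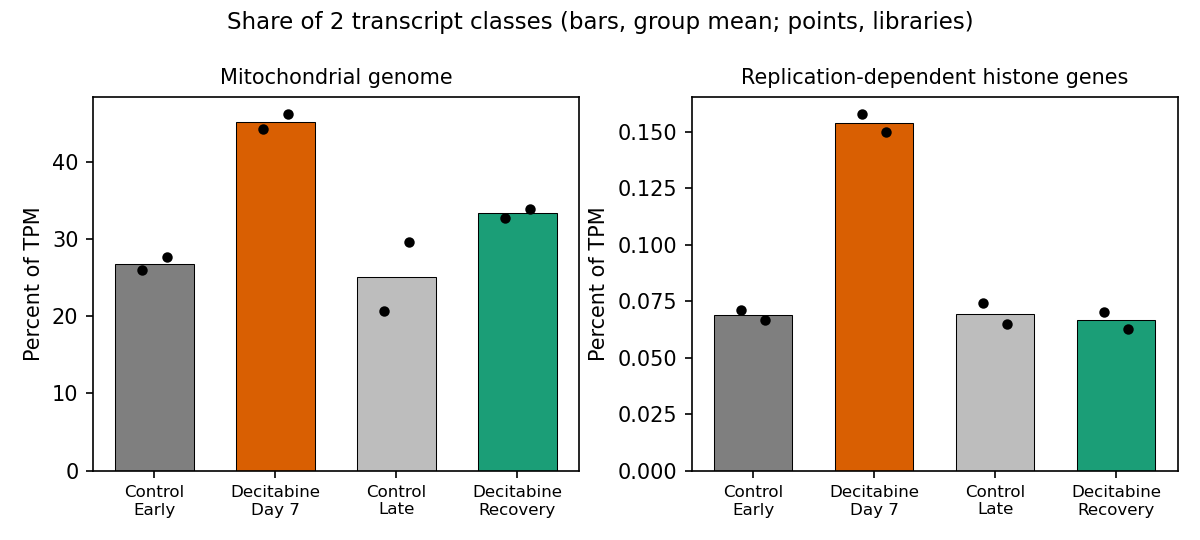
Share of TPM (percent) from the mitochondrial genome (left) and from replication-dependent histone genes (right), with bars for group means and points for the 2 libraries of each group. The mitochondrial share was 45.3% in Decitabine Day 7 against 26.9% in Control Early. Libraries were made from poly(A) RNA, so only histone transcripts captured by that selection are shown.

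Decitabine given for 7 days turned on genes that were near 0 in untreated TAMR cells. GSTP1, which encodes a glutathione transferase and whose promoter is a classic site of methylation in cancer (ENSG00000084207, GRCh38, chromosome 11, start 67583742, end 67586656), was listed at 0 in both Control Early libraries and stood at 138 and 125 TPM in the Decitabine Day 7 libraries (adjusted p = 4.87e-08). An endogenous retroviral envelope gene, cancer-testis antigens (45 of 61 without the low-value filter) and germline genes (24 of 50, with 4 lower) rose with it. The estrogen receptor gene ESR1, 72 of 79 proliferation genes and 25 of 26 cholesterol synthesis genes fell (45 and 19 for these lists with median-of-ratios scaling). Of these 4 lists, cancer-testis antigens alone kept their call by camera with an estimated correlation. That test covered only members that passed the low-value filter (17 cancer-testis antigens), which selects genes that treatment raised. All statements on single genes rest on limma with Benjamini-Hochberg adjustment and on 2 libraries per group.

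Cancer-testis antigens, proteins normally made only in the germline, rose as a group. The list holds 70 names, and 17 genes passed the low-value filter. As these genes lay near 0 in controls, they passed through the treated libraries, so that the share that rose among them was largely set by the filter. All 17 were higher at day 7, with a median log2 change of 2.45 (camera adjusted p = 4.59e-24, and adjusted p = 0.00876 with an estimated correlation), and all 17 when adjusted over the list alone. Without the filter 45 of 61 members were higher and 0 lower (camera adjusted p = 5.23e-27). These 61 members had some TPM in a library, and some of them may have had it only in treated libraries. SSX1, a transcriptional repressor of this class, was listed at 0 in both Control Early libraries and at 7.24 and 6.42 TPM at day 7 (adjusted p = 2.06e-06). PAGE2B was listed at 0 in both early controls and at 13.3 and 12.3 TPM at day 7 (adjusted p = 6.13e-07), with the reservation that PAGE2B, PAGE2 and PAGE5 are near-identical. Among germline genes known to be silenced by methylation, of which 15 of 56 passed the filter, 10 rose and 3 fell, or 10 and 4 when adjusted over the list alone, with a median of 1.32. Without the filter 24 of 50 rose and 4 fell. Their camera adjusted p was 1.52e-09, and adjusted p = 0.178 with an estimated correlation. DAZL, an RNA-binding protein of germ cells, was listed at 0 in both early controls and at 11.7 and 11.5 TPM at day 7. GTSF1, a partner of the piRNA pathway, stood at 0 and at 10.2 and 10.3 TPM (adjusted p = 6.26e-07 and 1.82e-06). STAG3, the cohesin subunit of meiosis, rose from 0.135 ± 0.0354 to 15.5 ± 1.84 TPM (SD, n = 2).

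Genes reported as silenced in breast tumours moved both ways: 16 of 34 rose and 13 fell, with the same counts adjusted over the list alone and a median of 0.09. The camera adjusted p was 1.24e-06, and adjusted p = 0.0763 with an estimated correlation; with median-of-ratios scaling 20 rose and 6 fell. UCHL1, a ubiquitin hydrolase, rose by 4.31 ± 0.08 (log2 ± SE) and SPARC, a matrix glycoprotein, by 4.42 ± 0.11, from 3.69 ± 0.0778 to 99.2 ± 0.884 TPM (SD, n = 2). ERVW-1, the retroviral envelope gene that encodes syncytin-1 (ENSG00000242950, GRCh38, chromosome 7, start 92468380, end 92477986), rose from 0.175 ± 0.0354 to 59.6 ± 4.32 TPM (SD, n = 2; log2 change 5.69 ± 0.10 SE, adjusted p = 1.18e-07). CRIP1, a small LIM-domain protein, rose from 1.24 ± 0.0707 to 186 ± 9.09 TPM (log2 change 6.39 ± 0.09 SE, adjusted p = 5.57e-08). Imprinted genes did not move together, with 4 of 21 higher and 11 lower, or 4 and 12 adjusted over the list alone, and 10 higher and 5 lower with median-of-ratios scaling (camera adjusted p = 0.103). H19, a long noncoding RNA expressed from the maternal allele (ENSG00000130600, GRCh38, chromosome 11, start 1995166, end 2004552), went from 11.2 and 12.9 TPM in Control Early to 815 and 782 TPM at day 7. PEG10, a retrotransposon-derived gene, went from 142 ± 7.07 to 557 ± 0.948 TPM.

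Interferon-stimulated genes were split. Of 48 measured members 19 rose and 13 fell, with the same counts adjusted over the list alone, a median of 0.17 and a camera adjusted p of 2.51e-09. The call was lost with an estimated correlation (adjusted p = 0.101), and with median-of-ratios scaling 34 rose and 4 fell. IFI27, a mitochondrial interferon-response protein, rose from 0.405 ± 0.276 to 39.6 ± 1.92 TPM (SD, n = 2), ISG15, a ubiquitin-like modifier, by 2.12 ± 0.16 (log2 ± SE) and IRF7, a transcription factor that drives interferon production, by 1.68 ± 0.21. Against Control Late, in which the list stood higher than in Control Early, 8 members were higher at day 7 and 27 lower, with a median of -0.39 and a camera adjusted p of 0.405. These counts are unscaled, and the median over all genes in that comparison was -0.46. Median-of-ratios scaling moved that all-gene median to 0.01, and the list was again not called (camera adjusted p = 0.688). For MHC class I presentation, 5 of 23 members rose and 9 fell (3 and 9 adjusted over the list alone). Its median of -0.01 and mean of -0.17 lay below 0 while camera, which compares the list with other genes, placed it upward at an adjusted p of 0.05 (adjusted p = 0.610 with an estimated correlation; 14 higher and 3 lower with median-of-ratios scaling). PSMB8, an immunoproteasome subunit, stood at 0 and 0.04 TPM in the early controls and at 2.87 and 3.30 TPM at day 7, whereas B2M, the light chain of class I molecules, fell by 1.23 ± 0.06 (scaled -0.58).

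Proliferation genes were lower at day 7. Of 79 members 72 fell and 0 rose, or 74 and 0 adjusted over the list alone, with a median of -0.92 (camera adjusted p = 8.23e-06; adjusted p = 0.492 with an estimated correlation). With median-of-ratios scaling 45 fell and 10 rose, with a median of -0.28. MKI67, a marker of cycling cells, went from 108 ± 0.297 to 31.8 ± 3.71 TPM (SD, n = 2; log2 change -1.73, scaled -1.09). PLK1, a mitotic kinase, and ECT2, a regulator of cytokinesis, fell by 1.79 ± 0.08 and 1.83 ± 0.07 (log2 ± SE; scaled -1.15 and -1.19). Cholesterol synthesis genes fell in 25 of 26 cases, also when adjusted over the list alone, with a median of -1.05 (camera adjusted p = 0.000723; adjusted p = 0.520 with an estimated correlation; 19 lower and 2 higher with median-of-ratios scaling). DHCR7, the last enzyme of the pathway, went from 157 ± 4.92 to 37.9 ± 2.09 TPM (SD, n = 2; scaled log2 change -1.38), and SREBF2, its main transcriptional activator, fell by 1.81 ± 0.08 (scaled -1.19). Chromatin looping factors, the group closest to the series' subject, fell in 26 of 28 cases and rose in 1, with the same counts adjusted over the list alone and a median of -0.94 (camera adjusted p = 0.0121; adjusted p = 0.492 with an estimated correlation; 15 lower and 4 higher with median-of-ratios scaling). Against Control Late 24 looping factors were lower and 0 higher, and the list was not called (camera adjusted p = 0.0746). Between the untreated groups 15 were lower and 1 higher in Control Late than in Control Early (camera adjusted p = 0.00575, and 0.811 with an estimated correlation). The fall at day 7 thus depends in part on the choice of control. SMC1A, a core cohesin subunit, fell by 2.28 ± 0.20 against Control Early (log2 ± SE, scaled -1.64).

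The DNA methylation machinery had 23 of 27 members lower and 3 higher, with the same counts adjusted over the list alone (camera adjusted p = 0.153; 12 lower and 9 higher with median-of-ratios scaling). DNMT1, the maintenance methyltransferase that decitabine traps, went from 85.0 ± 0.764 to 41.5 ± 0.219 TPM (SD, n = 2; log2 change -1.02, scaled -0.37), and TET1, which oxidises methylcytosine, from 1.80 ± 0.148 to 0.340 ± 0.0141 TPM (scaled -0.80). The de novo enzymes DNMT3A and DNMT3B and the DNMT1 partner UHRF1 had log2 changes of -0.46, -0.30 and -0.28, and these turned to 0.14, 0.29 and 0.36 with median-of-ratios scaling. Silencing complexes had 29 of 34 members lower and 1 higher, with the same counts adjusted over the list alone (camera adjusted p = 0.0472; adjusted p = 0.610 with an estimated correlation; 12 lower and 7 higher with median-of-ratios scaling).

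Estrogen response genes fell in 37 of 52 cases and rose in 9 (38 and 9 adjusted over the list alone), with a median of -0.79. Camera did not separate them from other genes (adjusted p = 0.799; 24 lower and 15 higher with median-of-ratios scaling). ESR1, the estrogen receptor gene (ENSG00000091831, GRCh38, chromosome 6, start 151656691, end 152129619), went from 2.79 ± 0.580 to 0.200 ± 0.0141 TPM (SD, n = 2; log2 change -1.65, scaled -1.40, adjusted p = 1.90e-05). Its targets GREB1 and TFF1 fell by 1.26 ± 0.10 and 1.26 ± 0.17 (log2 ± SE; scaled -0.87 and -0.62), and IGFBP5, a modulator of growth factor signals, by 1.74 ± 0.08, while the small heat shock gene HSPB8 rose by 1.76 ± 0.12. Luminal identity genes had 22 of 34 members lower and 7 higher, or 22 and 8 adjusted over the list alone (camera adjusted p = 0.725; 14 lower and 15 higher with median-of-ratios scaling). GATA3, a luminal transcription factor, went from 294 ± 2.69 to 145 ± 5.73 TPM (SD, n = 2; scaled log2 change -0.36), and KRT7, a simple epithelial keratin, rose from 31.1 ± 1.62 to 197 ± 13.8 TPM. FOXA1, a pioneer factor for the receptor, was not called at 54.4 ± 1.26 and 64.3 ± 2.07 TPM, and was called higher with median-of-ratios scaling (log2 change 0.88). Basal and mesenchymal genes split, with 12 of 27 higher and 11 lower and the same counts adjusted over the list alone (camera adjusted p = 7.95e-05; adjusted p = 0.492 with an estimated correlation; adjusted p = 0.0608, with 13 higher and 6 lower, after median-of-ratios scaling). KRT17, a basal keratin, rose from 0.165 ± 0.0778 to 14.5 ± 1.39 TPM (SD, n = 2), and MYL9, a myosin light chain of contractile cells, was listed at 0 in both early controls and at 10.9 and 10.3 TPM at day 7.

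Among p53 targets 11 of 48 rose and 20 fell, with the same counts adjusted over the list alone. The median was -0.08 while camera placed the list upward (adjusted p = 0.00346; adjusted p = 0.492 with an estimated correlation), and 25 rose and 8 fell with median-of-ratios scaling. GDF15, a stress-induced cytokine, rose from 12.9 ± 1.04 to 48.2 ± 0.0354 TPM (SD, n = 2). Replication-dependent histones rose in 32 of 42 cases and fell in 2, with the same counts adjusted over the list alone and a median of 0.79 (camera adjusted p = 5.64e-23; adjusted p = 0.0763 with an estimated correlation). H1-2, a linker histone, went from 113 ± 1.80 to 431 ± 8.51 TPM (SD, n = 2) and H3C2, a core histone, from 1.79 ± 0.453 to 9.68 ± 1.68 TPM. All histone values are those of poly(A) RNA, so histone transcripts that the selection did not capture are not counted. Mitochondrially encoded genes rose in 11 of 13 cases (12 adjusted over the list alone), with a median of 0.81 (camera adjusted p = 8.44e-11; adjusted p = 0.267 with an estimated correlation). Quantile normalization left 0 of 13 called higher or lower by limma, also adjusted over the list alone (camera adjusted p = 0.703). MT-CO1 and MT-ND2, subunits of respiratory complexes, rose by 0.93 ± 0.12 and 1.05 ± 0.15 (log2 ± SE). Ribosomal protein genes had 2 of 77 members higher and 30 lower (2 and 26 adjusted over the list alone) with a median of -0.13, and camera placed them upward (adjusted p = 0.0183; adjusted p = 0.842 with an estimated correlation). There were 63 higher and 1 lower after median-of-ratios scaling. Without the low-value filter camera placed the list downward and did not call it (adjusted p = 0.668).

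Immediate early genes, which respond within minutes to growth signals and handling, showed the widest gap to Control Early. All 27 members were higher at day 7, also when adjusted over the list alone, with a median of 2.75 (camera adjusted p = 3.38e-37; adjusted p = 0.0763 with an estimated correlation). FOS went from 3.11 ± 0.156 to 751 ± 94.9 TPM (SD, n = 2), and FOSB and EGR1, transcription factors of the same response, rose by 7.94 ± 0.17 and 6.28 ± 0.10 (log2 ± SE). DUSP1, a phosphatase that ends MAP kinase signals, rose by 4.60 ± 0.11 and HES1, a Notch target, by 4.91 ± 0.09. These levels were low in Control Early alone: against Control Late 12 of the 27 members were higher at day 7 and 8 lower, with a median of -0.18. These values are unscaled, and with median-of-ratios scaling the median was 0.40, so its direction depends on the scaling. Unscaled log2 changes against Control Late were 0.48 for FOS, -0.39 for EGR1, -0.17 for HES1 and -0.53 for DUSP1. With median-of-ratios scaling EGR1 and DUSP1 turned upward and were not called.

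Among the largest falls outside the lists were that of TRG-AS1, a noncoding RNA of the T cell receptor gamma locus (ENSG00000281103, GRCh38, chromosome 7, start 38330978, end 38378804), from 59.1 ± 2.83 to 5.13 ± 0.106 TPM (SD, n = 2). PI15, a secreted peptidase inhibitor, went from 10.3 ± 0.247 to 0.285 ± 0.00707 TPM, and CTNND2, a delta-catenin, from 42.6 ± 2.94 to 4.58 ± 0.184 TPM. Scaled log2 changes were -2.70, -2.82 and -2.38. TRG-AS1 overlaps TRGV genes on the other strand, and whether the counting used the strand is not stated. The remaining lists were not called: hypoxia and glycolysis (3 of 31 higher and 23 lower, adjusted p = 0.524), stress response (6 of 28 higher and 17 lower, adjusted p = 0.323), growth factor receptors (3 of 24 higher and 17 lower, adjusted p = 0.799), fibroblast and endothelial markers (2 of 6 higher and 3 lower, adjusted p = 0.153) and leukocyte markers (0 of 3 higher and 2 lower, adjusted p = 0.857). Counts adjusted over the list alone were the same in these 5 lists. Without the low-value filter camera called hypoxia and glycolysis lower (adjusted p = 0.00392) and none of the others. Median-of-ratios scaling gave 9 higher and 12 lower for hypoxia, 9 and 7 for stress response, 6 and 9 for growth factor receptors, 3 and 1 for fibroblast and endothelial markers and 1 and 1 for leukocyte markers.

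Over all 14570 genes tested, 1535 were higher and 9337 lower at day 7, of which 597 and 3098 changed at least 2-fold. With median-of-ratios scaling, 4707 were higher and 4643 lower, so that the higher share of calls went from 14.1% to 50.3%. All 1535 higher calls and 4643 of the 9337 lower calls were shared between both. Set against Control Late, also unscaled, 959 of the 1535 higher and 8014 of the 9337 lower calls remained. The median gene was lowered in both unscaled comparisons, which favours shared falls. With median-of-ratios scaling in both, 3210 of 4707 higher and 2941 of 4643 lower calls remained. Among 46360 transcripts 5879 were higher (3305 without Decitabine Day 7 replicate 1) and 20894 lower. In 2247 genes transcripts moved both ways, and 1303 genes had a called transcript while their sum was not called.

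**Figure D2:**
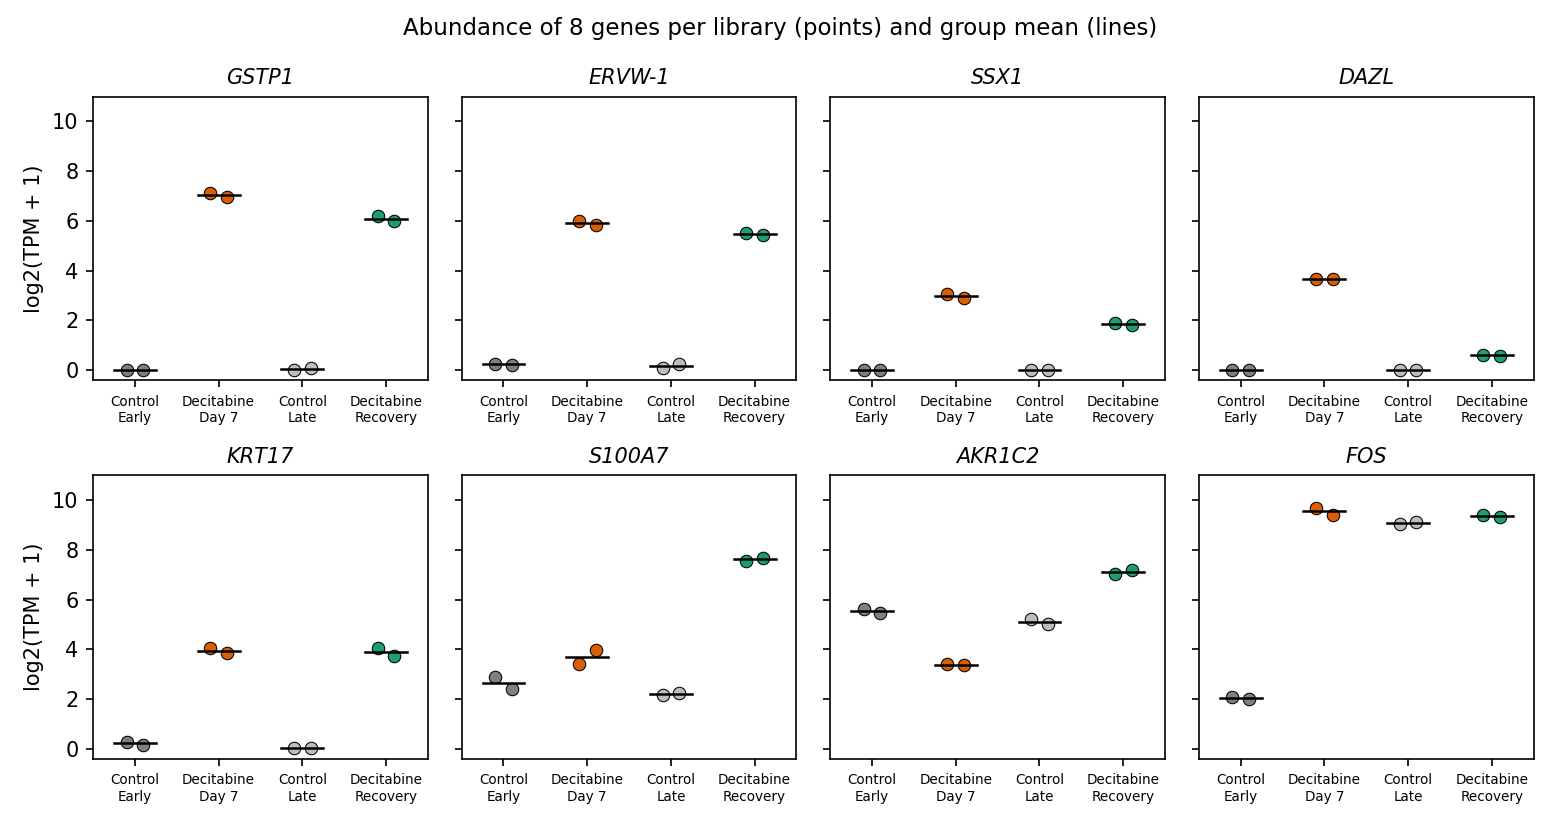
Abundance, as log2(TPM + 1), of 8 genes in each library (points) with group means (lines), in the order Control Early, Decitabine Day 7, Control Late and Decitabine Recovery. GSTP1, ERVW-1 and SSX1 lay near 0 in both controls and high after treatment, S100A7 and AKR1C2 were highest at recovery, and FOS was low in Control Early only.

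At day 35, after 28 drug-free days per the treatment protocol, part of the day 7 pattern was present and another part was not. GSTP1 stood at 71.4 and 62.6 TPM in the Decitabine Recovery libraries and at 0 and 0.05 TPM in Control Late (log2 change 6.05 ± 0.10 SE, adjusted p = 5.83e-07). Of cancer-testis antigens 32 of 61 (without the low-value filter) were higher than in Control Late, of basal and mesenchymal genes 18 of 27 and of p53 targets 21 of 48, and 55 of 79 proliferation genes were lower. Of these 4 lists, the first alone kept its call by camera with an estimated correlation. That test covered only the 17 cancer-testis antigens that passed the filter through treated libraries. S100A7 and LCN2, whose log2 rises at day 7 were 1.05 ± 0.21 and 1.14 ± 0.13 (SE), were among the largest rises. S100A7, an antimicrobial protein of inflamed epithelium (ENSG00000143556, GRCh38, chromosome 1, start 153457744, end 153460651), stood at 3.43 and 3.77 TPM in Control Late and at 189 and 206 TPM at recovery. LCN2, an iron-binding defence protein, went from 5.51 ± 1.07 to 98.9 ± 4.08 TPM (SD, n = 2). Adjusted p-values were 8.89e-06 and 5.11e-06.

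Of the 17 cancer-testis antigens that passed the filter through treated libraries, 16 were higher and 0 lower, also adjusted over the list alone, with a median of 1.22 (camera adjusted p = 4.52e-15; adjusted p = 0.0214 with an estimated correlation). Without the filter 32 of 61 were higher and 0 lower (camera adjusted p = 2.16e-18). SSX1 was listed at 0 in both late controls and at 2.72 and 2.49 TPM at recovery, and PAGE2 at 0 and at 2.49 and 2.81 TPM. Methylation-controlled germline genes had 10 of 15 members higher and 1 lower, also adjusted over the list alone, and 14 of 50 higher and 2 lower without the filter (camera adjusted p = 3.68e-06; adjusted p = 0.289 with an estimated correlation). GTSF1 was listed at 0 in Control Late and at 8.91 and 7.21 TPM at recovery, and STAG3 stood at 6.23 and 6.11 TPM against 0.09 and 0.13 TPM. DAZL stood at 0.540 and 0.470 TPM at recovery against 0.01 and 0 TPM. Genes silenced in breast tumours had 18 of 34 members higher and 6 lower (19 and 7 adjusted over the list alone), with a median of 0.49 (camera adjusted p = 3.95e-06; adjusted p = 0.178 with an estimated correlation). SPARC stood at 61.4 ± 9.80 TPM against 4.04 ± 0.113 (SD, n = 2), and TFPI2, a protease inhibitor, at 5.21 and 7.59 TPM against 0 and 0.07. ERVW-1 remained at 43.3 ± 1.48 TPM against 0.125 ± 0.0919 (SD, n = 2; log2 change 5.30 ± 0.10 SE). H19 stood at 102 ± 0.198 TPM against 4.96 ± 0.170, while the imprinted list as a whole had 5 of 21 members higher and 3 lower, also adjusted over the list alone (camera adjusted p = 0.672).

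Basal and mesenchymal genes rose in 18 of 27 cases and fell in 2 (20 and 2 adjusted over the list alone), with a median of 1.01 (camera adjusted p = 7.14e-12; adjusted p = 0.288 with an estimated correlation). KRT17 went from 0.025 ± 0.00707 to 13.8 ± 2.34 TPM (SD, n = 2). SERPINE1, an inhibitor of plasminogen activation, went from 0.270 ± 0.0424 to 20.1 ± 2.37 TPM, and EGFR, the epidermal growth factor receptor, from 1.25 ± 0.276 to 5.05 ± 0.615 TPM. MYL9 was listed at 0 in both late controls and at 15.4 and 12.3 TPM at recovery. Lists of fibroblast and endothelial and of leukocyte markers were not called, and few of their genes passed the filter (6 of 25 and 3 of 29). Epidermal markers were not a list. Fibroblast and endothelial markers had 2 of 6 members higher and 2 lower, also adjusted over the list alone (adjusted p = 0.825). Of 3 leukocyte markers limma called 0, also adjusted over the list alone, and 2 were lower at an unadjusted p under 0.05 (camera adjusted p = 0.552). Luminal identity genes had 9 of 34 members higher and 5 lower, also adjusted over the list alone (camera adjusted p = 0.0242; adjusted p = 0.501 with an estimated correlation). Without the low-value filter this call was lost (camera adjusted p = 0.126). KRT7 stood at 205 ± 18.3 TPM against 28.5 ± 5.35 (SD, n = 2), and SPDEF, a luminal transcription factor, fell by 1.31 ± 0.14 (log2 ± SE).

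Estrogen response genes had 16 of 52 members higher and 8 lower (17 and 9 adjusted over the list alone), with a median of 0.09 (camera adjusted p = 0.00430; adjusted p = 0.289 with an estimated correlation). The receptor gene itself, ESR1, was lower, at 1.45 ± 0.0495 against 3.48 ± 0.247 TPM (SD, n = 2; adjusted p = 0.00269), and GREB1, a list member and direct target, fell by 0.90 ± 0.10 (log2 ± SE). AGR2, a disulfide isomerase of secretory cells, rose by 1.44 ± 0.13, FHL2, a LIM-domain cofactor, by 1.68 ± 0.11 and HSPB8 by 1.39 ± 0.12. TFF1 was not called, at 91.9 ± 5.06 and 102 ± 24.9 TPM.

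Interferon-stimulated genes had 20 of 48 members higher and 2 lower (25 and 3 adjusted over the list alone), with a median of 0.28 (camera adjusted p = 9.08e-08; adjusted p = 0.223 with an estimated correlation). IFI27 went from 1.86 ± 0.820 to 70.8 ± 2.39 TPM (SD, n = 2) and XAF1, a pro-apoptotic interferon target, from 0.0950 ± 0.0212 to 4.42 ± 0.346 TPM, while IFIH1, a sensor of double-stranded RNA, fell by 1.51 ± 0.10 (log2 ± SE). CCL5, a chemokine that attracts T cells and lies outside the list, rose from 8.54 ± 1.30 to 166 ± 2.29 TPM. MHC class I genes were not called as a list, with 5 of 23 higher and 1 lower (4 and 1 adjusted over the list alone; camera adjusted p = 0.313). PSMB8 stood at 4.57 and 5.17 TPM at recovery against 0 and 0.06 TPM, and HLA-C, a class I heavy chain, rose by 0.47 ± 0.06.

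p53 targets rose in 21 of 48 cases and fell in 3 (23 and 5 adjusted over the list alone), with a median of 0.20 (camera adjusted p = 9.15e-06; adjusted p = 0.289 with an estimated correlation). CDKN1A, the cyclin-dependent kinase inhibitor p21, went from 32.4 ± 3.25 to 80.2 ± 4.63 TPM (SD, n = 2). BTG2, an antiproliferative factor, rose by 1.86 ± 0.08 (log2 ± SE), TP53INP1, a p53 cofactor, by 1.48 ± 0.09 and KITLG, the ligand of the KIT receptor, by 1.42 ± 0.09. Proliferation genes fell in 55 of 79 cases and rose in 0 (64 and 0 adjusted over the list alone), with a median of -0.34 (camera adjusted p = 2.56e-10; adjusted p = 0.289 with an estimated correlation; 38 lower and 0 higher with median-of-ratios scaling). CDK1, the mitotic kinase, fell by 0.75 ± 0.08, PTTG1, the securin, by 0.64 ± 0.06 and MAD2L1, a spindle checkpoint protein, by 0.65 ± 0.09 (log2 ± SE). MKI67 was not called, at 72.7 ± 9.48 and 64.9 ± 0.148 TPM (SD, n = 2).

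**Figure D3:**
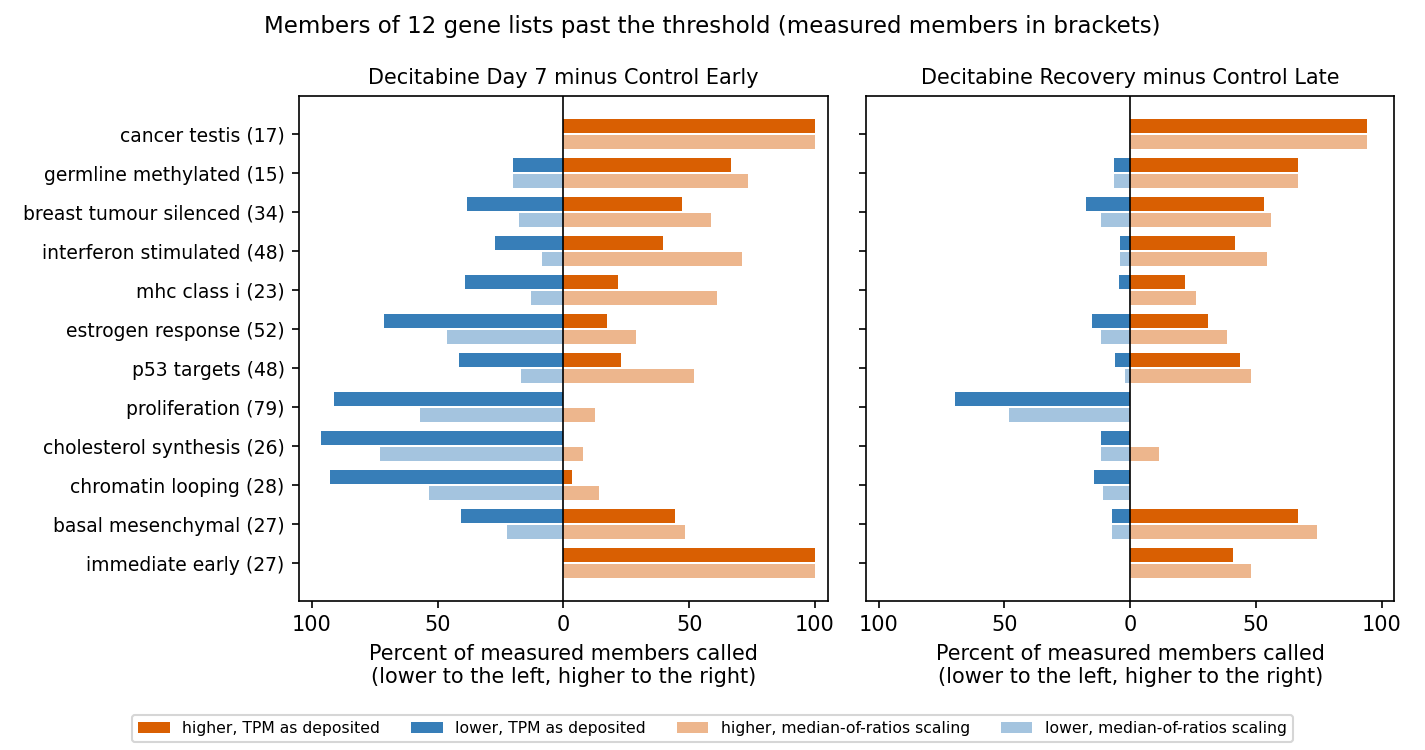
Percent of measured members of 12 gene lists called lower (left of 0) or higher (right of 0) in Decitabine Day 7 minus Control Early and Decitabine Recovery minus Control Late, with dark bars for TPM as deposited and pale bars after median-of-ratios scaling. All 17 cancer-testis genes that passed the low-value filter were higher at day 7 under both, and 16 of 17 at recovery.

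Immediate early genes at recovery had 11 of 27 members higher and 0 lower (12 and 0 adjusted over the list alone; median 0.29, camera adjusted p = 2.64e-06, adjusted p = 0.311 with an estimated correlation). Ribosomal protein genes had 14 of 77 lower and 0 higher, and 0 and 0 adjusted over the list alone (median -0.26, camera adjusted p = 4.69e-06, adjusted p = 0.822 with an estimated correlation; 5 lower and 0 higher with median-of-ratios scaling), beside Control Late libraries in which their share was 18.1% and 14.8% of TPM. Mitochondrially encoded genes had 2 of 13 higher and 0 lower, or 7 and 0 adjusted over the list alone (median 0.41, camera adjusted p = 0.000323, adjusted p = 0.554 with an estimated correlation), beside the unequal mitochondrial shares of the Control Late libraries. Replication-dependent histones (3 of 42 higher and 4 lower, adjusted p = 0.992), chromatin looping factors (0 of 28 higher and 4 lower, adjusted p = 0.992), cholesterol synthesis (0 of 26 higher and 3 lower, adjusted p = 0.992), the DNA methylation machinery (3 of 27 higher and 2 lower, adjusted p = 0.825) and silencing complexes (1 of 34 higher and 10 lower, adjusted p = 0.156) were not called by camera. Neither were hypoxia and glycolysis (4 of 31 higher and 6 lower, adjusted p = 0.825), stress response (5 of 28 higher and 9 lower, adjusted p = 0.767) and growth factor receptors (4 of 24 higher and 5 lower, adjusted p = 0.334). Adjusted over the list alone, these counts were 3 and 3 for histones, 0 and 3 for looping factors, 0 and 0 for cholesterol synthesis, 2 and 1 for the methylation machinery, 2 and 15 for silencing complexes, 4 and 6 for hypoxia, 6 and 12 for stress response and 5 and 5 for growth factor receptors. Cholesterol synthesis genes went 3 each way with median-of-ratios scaling. DNMT1 stood at 66.5 ± 1.36 TPM at recovery and 71.0 ± 0.636 in Control Late, DHCR7 at 121 ± 7.67 and 128 ± 6.36, and H1-2 at 104 ± 8.86 and 119 ± 18.5 (SD, n = 2), none of them called.

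Among genes outside the lists, FABP7, a fatty acid binding protein, rose from 0.220 ± 0.0424 to 24.2 ± 2.57 TPM (SD, n = 2), and S100P, a calcium-binding protein, from 12.5 ± 3.43 to 236 ± 9.98 TPM. Among the largest falls were those of PI15, from 14.3 ± 4.42 to 0.580 ± 0.339 TPM, and CPM, a membrane carboxypeptidase, from 79.7 ± 10.6 to 10.1 ± 3.26 TPM, and TRG-AS1 stood at 9.46 ± 0.156 TPM against 56.7 ± 2.32. In all, 1649 genes were higher and 2722 lower at recovery, with 485 and 140 changed at least 2-fold. Median-of-ratios scaling gave 2256 higher and 1800 lower, moving the higher share of calls from 37.7% to 55.6%. The lower count depended on single libraries: it was 4860 without Control Late replicate 2, 870 without Decitabine Recovery replicate 1 and 614 without Decitabine Recovery replicate 2. The higher count was 821 and 881 without Decitabine Recovery replicates 1 and 2. Among transcripts 1301 were higher and 1213 lower, and these also rested on single libraries. They were 4069 and 6575 without Control Late replicate 2, 316 and 152 without Decitabine Recovery replicate 1 and 332 and 125 without Decitabine Recovery replicate 2. Without Control Early replicates 1 and 2 they were 727 and 317, and 723 and 318, and without Decitabine Day 7 replicates 1 and 2 they were 803 and 402, and 802 and 402. In the recovery comparison 12 genes had transcripts moving both ways, and 286 had a called transcript while their sum was not called.

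The effects at the 2 times were then compared directly. For cancer-testis antigens the effect was smaller at recovery in 14 of 17 members and larger in 0, also adjusted over the list alone (camera adjusted p = 8.52e-16; adjusted p = 0.0207 with an estimated correlation). These members passed the filter through treated libraries. Where those were of day 7, the choice favours a smaller effect at recovery, and the difference was not tested without the filter. The fall of cholesterol synthesis genes was smaller at recovery in 22 of 26 members (23 adjusted over the list alone; camera adjusted p = 0.000493, adjusted p = 0.618 with an estimated correlation). AKR1C2, a reductase of steroids and carbonyls (ENSG00000151632, GRCh38, chromosome 10, start 4987775, end 5018031), fell at day 7 from 45.2 ± 3.73 to 9.46 ± 0.163 TPM and rose at recovery from 33.8 ± 3.15 to 136 ± 11.3 TPM (SD, n = 2), a difference of effects of 4.12 ± 0.14 (log2 ± SE, adjusted p = 1.32e-05). The S100A7 difference was 4.38 (adjusted p = 8.45e-05). That of FOS was -7.23, which followed its low level in Control Early. Of the 1535 genes higher at day 7, 631 (41.1%) were higher at recovery, 65 were lower and 839 were not called. Lists of these sizes drawn independently would share 174. Of the 9337 lower at day 7, 2227 (23.9%) were lower at recovery and 637 higher, against 1744 for independent lists. The comparisons share no library, but both tests use the same spread estimate of each gene, fitted to all libraries. Independent lists may therefore set too low a mark for the overlap. With median-of-ratios scaling 1235 of 4707 rises (26.2%) and 799 of 4643 falls (17.2%) were kept. Among rises of at least 4-fold at day 7, 118 of 176 (67.0%) were kept, and among such falls 42 of 125 (33.6%). The kept share of all falls was 5.76% without Decitabine Recovery replicate 2 and 37.9% without Control Late replicate 2. The difference of effects was positive in 7297 genes and negative in 1074, and these became 3913 and 3822 with median-of-ratios scaling. The negative count was 603 without Decitabine Day 7 replicate 1, 713 without Control Early replicate 2 and 2124 without Control Late replicate 2.

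Untreated cells also changed between day 11 and day 35. Immediate early genes rose from Control Early to Control Late in 26 of 27 cases and fell in 1, also adjusted over the list alone, with a median of 2.95 (camera adjusted p = 1.41e-35; adjusted p = 0.0852 with an estimated correlation). FOS rose by 7.03 ± 0.09, FOSB by 6.97 ± 0.17, EGR1 by 6.67 ± 0.10, DUSP1 by 5.13 ± 0.11 and HES1 by 5.08 ± 0.09 (log2 ± SE). Interferon-stimulated genes rose in 32 of 48 cases and fell in 1 (35 and 1 adjusted over the list alone), with a median of 0.39 (camera adjusted p = 1.48e-17; adjusted p = 0.0852 with an estimated correlation). MHC class I genes rose in 7 of 23 and fell in 2 (8 and 2 adjusted over the list alone; 13 and 1 with median-of-ratios scaling; camera adjusted p = 0.000443, adjusted p = 0.811 with an estimated correlation). Cancer-testis antigens stayed near 0 in both control groups. Without the filter limma called 0 of 61 in either direction, also adjusted over the list alone, and 0 were higher and 1 lower at an unadjusted p under 0.05 (camera adjusted p = 0.504). Proliferation genes fell in 36 of 79 cases and rose in 0 (43 and 4 adjusted over the list alone; 30 and 6 with median-of-ratios scaling; camera adjusted p = 0.000128; adjusted p = 0.811 with an estimated correlation). Camera also placed ribosomal proteins upward (adjusted p = 1.12e-08), though limma called 0 of 77, also adjusted over the list alone. Stress response genes rose in 11 of 28 cases and fell in 3 (12 and 3 adjusted over the list alone, camera adjusted p = 1.26e-05). Chromatin looping factors rose in 1 of 28 and fell in 15 (2 and 17, camera adjusted p = 0.00575). With an estimated correlation each had an adjusted p of 0.811. Counts over all genes were 902 higher and 3188 lower, or 1942 and 2240 with median-of-ratios scaling. They rested on single libraries, with 216 higher and 316 lower without Control Early replicate 1, 240 and 522 without Control Early replicate 2, and 3440 higher without Control Late replicate 2.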

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

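The tests of the immediate early genes, of the nuclear genes and of the other cell types were chosen only after the result was seen, and the test of whether basal genes already rose at day 7 was written before. The bounds for the nuclear genes and for KRT5 and KRT14 were also revised after their values were seen. The values for lists and named genes that close this section are differences between the effect at recovery and the effect at day 7. They were noted because a test of that difference passed the threshold. The nuclear genes are given at day 7. Basal and mesenchymal genes are given at recovery, and the test of their difference did not pass (camera adjusted p = 0.469).

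Immediate early genes stood 2.75 (median log2) above Control Early at day 7 and their effect differed between the times (camera adjusted p = 6.66e-31; adjusted p = 0.0806 with an estimated correlation, which is no call). Low levels in the Control Early libraries are a candidate explanation that the tables go along with: 26 of 27 members were lowest in that group, and the median against Control Late was -0.18 unscaled and 0.40 with median-of-ratios scaling, far below the 3.28 found against Control Early on that scale. A rise with decitabine stays open beside it, since 12 members were higher than in Control Late both unscaled and scaled and 8 were lower unscaled. How the early controls were fed or handled before harvest is not recorded in the labels, so neither account can be taken further.

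The median nuclear gene lay at -0.54 at day 7, beside a mitochondrial share of 45.3% of TPM. The larger mitochondrial share as the whole cause stays open, since rescaling to nuclear genes left the median at -0.20 against Control Early but at -0.09 against Control Late, and the controls themselves differed by -0.08. A trend with transcript length stays open too: the shortest sixth of 12014 protein-coding genes lay 0.70 above the longest sixth, while the Control Early replicates differed by 0.01 over the same classes. The length difference was 0.23 against Control Late, 0.43 between the controls, and 0.35 between the Control Late replicates, so part of the shift may follow length for technical reasons such as RNA integrity, and the choice of control keeps both open. A real loss of nuclear messenger RNA under decitabine was not tested, because TPM carries no absolute scale.

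Basal and mesenchymal genes were higher at recovery in 18 of 27 cases. Basal keratinocytes as the source of KRT5 are argued against by KRT14, which reached at most 0.0327 of KRT5 in a recovery library (means 0.0850 and 4.25 TPM), and fibroblasts by VIM, COL1A2 and COL3A1, whose highest mean at recovery was 0.335 TPM. Other keratinocytes stay open: KRT5 or KRT14 reached at most 0.313 of KRT17, but KRT5 rose from 0.0550 TPM, and, chosen after their values were seen, KRT6A stood at 1.69 and 1.79 TPM, IVL at 2.51 and 2.22, SPRR3 at 2.83 and 2.55, SPRR1B at 2.5 and 2.07 and SPRR2D at 3.58 and 2.45, the last 2 listed at 0 in the 6 other libraries. A change of the treated cells that began during treatment stays open. Of the 18 members, 9 were also higher at day 7 with median-of-ratios scaling. Over all genes, with both calls on that scaling, 1235 of the 2256 higher at recovery were also higher at day 7. The share of the group thus does not stand out, and it cannot decide the question. Selection of a subset of cells during the drug-free period was not tested.

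Among lists, cancer-testis antigens (camera adjusted p = 8.52e-16), germline genes (2.29e-06), replication-dependent histones (2.11e-22), mitochondrially encoded genes (3.53e-06), ribosomal proteins (5.78e-09) and interferon-stimulated genes (0.0455) had a lower effect relative to other genes at recovery. With an estimated correlation cancer-testis antigens kept the call (adjusted p = 0.0207), and it was lost for germline genes (0.489), histones (0.0806), mitochondrial genes (0.618), ribosomal proteins (0.751) and interferon-stimulated genes (0.618). Of the 48 interferon-stimulated genes 17 had a larger effect at recovery and 8 a smaller one, with a median of 0.13. The unscaled median of this difference over all genes was 0.44. Fry, which tests a list against no change, placed the interferon-stimulated genes upward (adjusted p = 0.026). With median-of-ratios scaling 6 of them were larger and 22 smaller, with a median of -0.26, so the direction of the counts depends on the scaling. Cholesterol synthesis (0.000493), proliferation (0.0368) and chromatin looping (0.0161) had a higher one. None of the 3 was called with an estimated correlation (0.618, 0.751 and 0.618), and the last 2 also not with median-of-ratios scaling (0.696 and 0.0512).

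Named genes whose effect differed numbered 55 of 70, and 4 of these (PSMB8, GATA3, MAD2L1 and HLA-C) did not with median-of-ratios scaling. Smaller effects at recovery, as log2 differences that rest on the pseudocount where a control is listed at 0, were -0.9991 for GSTP1, -2.94 for CRIP1, -1.83 for H19, -0.39 for ERVW-1, -0.77 for UCHL1, -0.79 for SPARC and -0.97 for PEG10. Germline and cancer-testis genes gave -2.16 for PAGE2B, -1.16 for PAGE2, -1.12 for SSX1, -3.07 for DAZL and -1.17 for STAG3. Differences that involve the low Control Early levels were -7.23 for FOS, -7.58 for FOSB, -6.08 for EGR1, -5.05 for HES1, -4.78 for DUSP1, -1.93 for ISG15 and -1.36 for IRF7. GDF15 gave -1.15, the histones H1-2 and H3C2 -2.11 and -2.02, and MT-CO1 and MT-ND2 -0.52 and -0.64.

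Positive differences, where a fall was smaller or a rise larger at recovery, were 0.78 for ESR1, 1.38 for TFF1, 0.80 for GATA3, 1.87 for IGFBP5, 1.58 for MKI67, 1.56 for PLK1, 1.56 for ECT2 and 0.36 for MAD2L1. DHCR7 gave 1.94, SREBF2 1.65, DNMT1 0.93, TET1 0.78, SMC1A 2.37, TRG-AS1 0.83, CTNND2 2.73 and B2M 1.23. Rises that were larger at recovery gave 4.38 for S100A7, 1.37 for S100P, 2.78 for SERPINE1, 2.81 for LCN2, 1.19 for BTG2, 1.04 for XAF1, 1.04 for FHL2, 2.21 for TFPI2 and 0.51 for PSMB8. CDKN1A (1.88), KITLG (2.35), AGR2 (2.28) and EGFR (1.95) rose at recovery without a called rise at day 7, and for CDKN1A and EGFR the sign at day 7 depended on the scaling. TP53INP1 (1.501) and HLA-C (0.46) were called higher at day 7 only with median-of-ratios scaling.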

How the results depend on the processing

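The tests with nuclear-only rescaling, the control of the other time and removal of the length trend were chosen only after the result was seen. Cancer-testis calls held in each setting that tested the list (a mean of at least 5 TPM left no test of it), and no named gene lost its call where it was tested with a library left out (DAZL was not tested without a Decitabine Day 7 library, nor TFPI2 without a Decitabine Recovery library). Read depth is unknown. Except for fewer genes or samples tested, the cause of each change was not tested.

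With an estimated correlation, adjusted p at day 7 was 0.101 for interferon, 0.61 for MHC class I, 0.492 for proliferation and 0.492 for p53, and at recovery 0.223, 0.289 for estrogen response, 0.289 for proliferation and 0.289 for p53. With fry, MHC class I (0.023) and p53 (0.0111) turned lower at day 7 and estrogen response was called lower (6.24e-05). Fry tests a list against no change, whereas camera compares it with other genes. It ran on unscaled values, where the median over all genes at day 7 was -0.54. These lower calls thus do not separate the lists from that shift and do not contradict camera.

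Median-of-ratios scaling gave 4707 higher and 4643 lower genes at day 7, 1800 lower at recovery, 3913 and 3822 for the difference, 1942 higher with culture time, 26.2% of rises kept, 0.0516 for MHC class I at day 7, and 11846 and 12790 transcripts at day 7. Quantile normalization gave 4101 and 5306, 3990 and 3587, 1659, 24.5%, 0.116, and 11493 and 12290 transcripts; MT-CO1, MT-ND2 and DAZL at recovery lost their calls. Of other lists called at day 7, it ended the calls of mitochondrially encoded genes (0.703), basal and mesenchymal genes (0.116), chromatin looping (0.119) and silencing complexes (0.669), and at recovery those of mitochondrially encoded genes (0.895) and ribosomal proteins (0.124). Nuclear genes only gave 3337 higher at day 7, 2528 and 1409 at recovery, 2340 negative differences, 12.9% of falls kept, 10057 higher transcripts at day 7 and 785 lower at recovery. Removing the length trend gave 4476 and 4526 at day 7, 3443 and 3246 differences, 1832 and 1843 with culture time, and 0.143 for MHC class I, and TET1 at day 7 lost its call (-0.03).

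Against the control of the other time, 5079 genes were lower at recovery, 46.5% of falls were kept, interferon at day 7 had 0.405, MHC class I 0.944 (reversed) at day 7 and 0.000135 at recovery, and EGR1 (-0.39), HES1 (-0.17) and DUSP1 (-0.53) reversed. Among secondary lists at day 7, chromatin looping (0.0746), silencing complexes (0.144) and ribosomal proteins (0.944) lost their camera calls, and imprinted genes were called higher (0.0274). At recovery ribosomal proteins lost theirs (0.91). Chromatin looping (0.0125) and silencing complexes (0.0357) were called lower there and stress response (0.00869) higher. Scaled as well, day 7 gave 3947 and 3656 and recovery 2919 higher, with 0.688 for interferon, 0.987 for MHC class I (reversed), 0.0533 for proliferation and 9.77e-05 for MHC class I at recovery; EGR1 (0.19), DUSP1 (0.05), IGFBP5 (-0.23) and TET1 (-0.29) at day 7 lost their calls.

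A mean of at least 5 TPM gave 688 higher at day 7, 863 at recovery, 563 negative differences, 549 with culture time, 0.0843 for MHC class I, and 1810 and 8850 transcripts at day 7 and 624 higher at recovery. No filter gave 2746 higher at day 7, 15.4% of falls kept, 0.84 for MHC class I, 0.0151 for estrogen response and 0.23 for p53 at day 7, and 581 lower transcripts at recovery. At day 7 camera then also called hypoxia and glycolysis (0.00392) and the DNA methylation machinery (0.000379) lower and imprinted genes (0.0141) higher. At recovery it called silencing complexes lower (0.00274). Ribosomal proteins at day 7 (0.668) and luminal identity at recovery (0.126) lost their calls. A pseudocount of 5 gave 0.0559 for MHC class I, and no trend 733 lower transcripts at recovery. Only the comparison's 4 samples gave 926 and 671 at recovery, 268 and 60 transcripts, 372 and 1194 with culture time, and 0.899 for estrogen response at day 7 (reversed). Tested against 2-fold, 300 and 1190 passed at day 7 and 211 and 37 at recovery.

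Leaving out 1 library, with a lone sample assumed to vary like the other groups, gave 1028 to 1838 higher and 8096 to 9915 lower at day 7. At recovery the higher count ran from 821 (Decitabine Recovery 1; 881 without Decitabine Recovery 2) to 2202, and the lower from 614 (Decitabine Recovery 2) to 4860 (Control Late 2), with 870 without Decitabine Recovery 1 and 1655 and 1654 without Control Early 1 and 2. Differences were 6094 to 8441 positive and 603 (Decitabine Day 7 replicate 1) to 2124 (Control Late 2) negative, with 713 without Control Early 2. Culture time gave 216 (Control Early 1; 240 without Control Early 2) to 3440 (Control Late 2) higher and 316 (Control Early 1; 522 without Control Early 2) to 3728 lower. Rises kept ran from 30.9% to 47.0% and falls from 5.76% (Decitabine Recovery 2) to 37.9% (Control Late 2), with 8.51% without Decitabine Recovery 1 and 15.5% and 15.4% without Control Early 1 and 2. MHC class I at day 7 ran from 0.023 to 0.116 (Control Early 2), and 0.0683 without Decitabine Day 7 replicate 2; estrogen response ran from 0.659 to 1, turning upward without Control Late 1 (0.992). Transcripts at day 7 ran from 3305 (Decitabine Day 7 replicate 1) to 6975 higher and 14565 to 22593 lower. At recovery they ran from 316 (Decitabine Recovery 1) to 4069 (Control Late 2) higher (332 without Decitabine Recovery 2, 727 and 723 without Control Early 1 and 2, 803 and 802 without Decitabine Day 7 replicates 1 and 2) and 125 (Decitabine Recovery 2) to 6575 (Control Late 2) lower (152 without Decitabine Recovery 1, 317 and 318 without Control Early 1 and 2, 402 without either Decitabine Day 7 library).

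Replicate numbers gave no sign of pairing the samples: replicate differences correlated at -0.13 to 0.10 between groups, and 4 of 8 libraries matched best with their own number. The 2 libraries of a group always give the same answer in that match, so the 8 are not separate checks. With the number as a block, counts were 1569 and 9411 at day 7, 1659 and 3009 at recovery, 7405 and 1146 for the difference and 1012 and 3040 with culture time.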

Other observations

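The X chromosome test and the first test of retention were written before their results were seen, and the tests of lists among genes off in controls, the retention tests against both controls and the choice of late-rising genes came after.

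Protein-coding genes that were off in the 4 control libraries (mean below 0.1 TPM) and reached 1 TPM in both libraries of a treated group numbered 104 of 6560 at day 7 and 65 at recovery, with 42 in both. Beyond the genes described above they held, chosen after their values were seen, NCCRP1, a gene of stratified epithelium, at 18.3 and 16.9 TPM at day 7 and 10.3 and 9.74 TPM at recovery, and CTSZ, a lysosomal protease, at 16.1 ± 0.148 TPM at day 7 and 4.37 ± 0.417 TPM at recovery (SD, n = 2). PLAU, the urokinase gene, stood at 6.20 and 6.32 TPM at day 7 and 4.90 and 4.87 TPM at recovery, and SLFN11, a protein that sensitises cells to DNA damage, at 4.23 and 3.47 TPM and 3.52 and 3.01 TPM. SYCP3, of the synaptonemal complex, reached 7.31 and 6.89 TPM at day 7 and 1.05 and 0.770 TPM at recovery. In the other direction, of 11151 genes expressed in every control library, 2 were off at day 7 (ENSG00000258677 and ENSG00000260537, chosen after their values were seen) and 0 at recovery.

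Another set was called higher at recovery but not at day 7. Day 7 was set only against Control Early for this choice, and a missing call does not show that a gene did not rise. There were 632 genes called higher at recovery and not called higher at day 7 unscaled or with median-of-ratios scaling, and whose difference of effects was called positive both ways. Chosen after their values were seen, these include GPX2, a glutathione peroxidase, at 29.0 ± 2.20 TPM at recovery (SD, n = 2) against 3.27 in Control Late, 5.52 at day 7 and 10.6 in Control Early. CSTA, a cysteine protease inhibitor of the epidermis, stood at 4.76 and 6.75 TPM against 0.17 and 0.09 TPM in Control Late, and KRT1, a keratin of differentiating epidermis, at 5.80 and 4.20 TPM against 0.14 and 0.07 TPM. AHR, the aryl hydrocarbon receptor, stood at 12.1 ± 1.62 TPM (SD, n = 2) against 2.33 in Control Late, 2.73 at day 7 and 7.05 in Control Early. COL17A1, a hemidesmosome collagen, stood at 7.03 ± 0.537 TPM against 0.930 in Control Late, 0.440 at day 7 and 3.22 in Control Early, and HLA-DPA1, an MHC class II chain, at 3.88 ± 0.651 TPM against 0.210 in Control Late. GPX2, AHR and COL17A1 fell between the controls, so their rise set against Control Early is smaller.

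A first hypothesis was that genes on the X chromosome are over-represented among those switched on at day 7, as many cancer-testis antigens lie there. On X lay 26 of the 104 genes, against 424 of 6560 (6.46%) of all protein-coding genes off in controls, with an odds ratio of 5.07 (95% interval 3.09 to 8.10, Fisher's exact test, two-sided p = 1.14e-09). Of the 26 genes, 16 belong to the cancer-testis list, and without that list 10 of 88 lay on X (Fisher's exact test, odds ratio 2.20, 95% interval 1.01 to 4.31, p = 0.0304). Leaving out the listed names does not remove cancer-testis genes that the list may lack, so whether the hypothesis holds beyond that class stays open. Genes are also not independent replicates, and gene families on X switch on together.

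Because the low-value filter selects genes that treatment raised, the lists were also tested among all protein-coding genes off in controls, where the filter plays no part. At day 7, 16 of 67 cancer-testis antigens (23.9%) were switched on against 88 of 6493 other genes (1.36%; Fisher's exact test, odds ratio 22.8, 95% interval 11.7 to 42.6, two-sided p = 2.82e-15), and 6 of 42 germline genes (14.3%) against 98 of 6518 (odds ratio 10.9, 95% interval 3.67 to 27.0, p = 4.54e-05). At recovery 8 of 67 cancer-testis antigens (11.9%) stood on against 57 of 6493 (0.878%; Fisher's exact test, p = 2.46e-07), and 2 of 42 germline genes (4.76%) against 63 of 6518 (0.967%; p = 0.0646). Near-identical family members are not independent, so these p-values are too small.

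A second hypothesis was that rises of genes off in controls are kept better than rises of genes already expressed. Among rises of at least 4-fold at day 7, immediate early genes left out, 51 of 57 (89.5%) off genes and 35 of 69 (50.7%) expressed genes were called higher at recovery (Fisher's exact test, two-sided p = 2.56e-06). Among rises of that size against both control groups the shares were 49 of 55 (89.1%) and 21 of 22 (95.5%), with p = 0.666 (Fisher's exact test), but there the choice of genes and the call at recovery share the Control Late libraries, which favours retention. With Control Late replicate 1 for the rise and replicate 2 for the call, the shares were 49 of 56 (87.5%) and 21 of 22 (95.5%, Fisher's exact test, p = 0.429), and with the libraries exchanged 48 of 55 (87.3%) and 21 of 24 (p of 1). In every one of these tests, the first included, off (below 0.1 TPM) and expressed (at least 1 TPM) were set by the mean of all 4 control libraries. Control Late thus entered the choice of off genes, which favours their call at recovery. Exchanging the libraries does not remove that. The few expressed genes leave the tests against both control groups little power. Retention by starting level therefore stays open, and genes that were low in Control Early may account for the first difference.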
